A study of Homo sapiens with 8 samples.

How the data were processed

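RNA from primary human endometrial stromal cells was measured on 8 one-colour Affymetrix arrays of 22277 probe sets. The cells came as 2 independent cultures from different donors, each treated with siREA or siGL3 and then with 10 nM estradiol, 1 µM progesterone and 0.5 µM 8-bromo-cAMP for 24 h or 96 h, so each of the 4 groups held 2 arrays, 1 per culture. The stated sources differ on how long the cells were exposed to siRNA before the hormones. The values deposited are intensity on a linear scale, 1 per probe set and array, from biotin-labelled cRNA. They lay near a common distribution over the arrays. The summary, background correction and normalization are not given in the sources used here, and the deposited table holds no detection calls. The upper quartile of intensity ran from 351.2 to 395.9 and the highest value from 16103 to 18170 per array.

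Values were used as log2(intensity + 16), with no further scaling. Of the probe sets, 19070 carried 1 gene symbol, 1043 carried several and 2164 none, and the last 2 kinds were left out. Gene names were matched to RefSeq by Entrez number for 19058 probe sets and 9 symbols were updated. No coordinates were used. Each of 11936 genes was represented by its probe set with the highest mean log2 value, and genes whose mean lay in the lowest 25% of the means of all probe sets were left out, which left 9523 genes. HOXA10, a gene planned to be named, was among those not tested. XIST and Y-linked genes were removed before any test.

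Each gene was fitted with limma (lmFit and eBayes) over all 8 arrays with a term for each of the 4 groups and a term for the culture, because the label protocol says that the cultures were split over the siRNAs. This left 3 residual degrees of freedom, to which the prior added 5.65. Whether the numbers pair the arrays was checked by correlating, across genes, the difference between the cultures in 1 group with that in another, and the 6 pairs of groups gave r from -0.0026 to 0.464 with a median of 0.274. The comparisons were knockdown at 24 h, at 96 h and averaged over both times, the change from 24 h to 96 h in siGL3 and in siREA cells, and the interaction of knockdown with time. A gene was called when its p-value, adjusted over all genes by Benjamini and Hochberg, was under 0.05. All p-values of single genes come from limma, and errors are standard errors of the log2 difference. The text names, per comparison, the 12 genes with the largest rise and the 12 with the largest fall among called genes with the same sign in both cultures (at both times for the average), up to 4 members of each list by smallest p, and PHB2, PHB1, PRL, IGFBP1, BMP2, WNT4, FOXO1, HAND2, PGR and ESR1.

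Gene lists covered 24 groups: decidual markers, responses to progestin, estrogen and cAMP, steroid receptors and coregulators, cell division, respiratory chain, mitochondrial chaperones and proteases, integrated stress response, endoplasmic reticulum chaperones, interferon response, inflammation, cholesterol synthesis, extracellular matrix, contractile cytoskeleton, p53 targets, hypoxia and glycolysis, BMP and SMAD targets, proteasome, and markers of stromal, epithelial, endothelial, leukocyte, and smooth muscle or pericyte cells. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, with camera at an estimated correlation and with fry as alternatives. The estimated correlation rests on 3 residual degrees of freedom, so camera has little power with it and a missing call there does not decide against a list. Counts adjusted over the list alone come from the single-gene p-values of its members. The lists, the comparisons, the rule for naming genes and the alternatives were fixed before the data were examined.

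The alternatives were no culture term, only the arrays compared, quantile normalization, median centring, no filter on low genes, the lowest 50% left out, every probe set, an intensity trend in eBayes, 1 or 64 added before the log, and leaving out each array in turn, where the remaining array of a group is assumed to vary like the other groups. The 2 cultures per group are too few to test single arrays as outliers by range. Fits on only the arrays compared hold 2 arrays per group and a culture term, which barely measures a gene's own spread. Very low p-values from that setting therefore carry little weight. The fit was tested on simulated data with the same design. Of genes shifted by a log2 value of 1, the share recovered was 91% for knockdown at 24 h, 88% at 96 h, 97% for the average and 42% for the interaction, and 99%, 100%, 100% and 97% at a shift of 2. For the time courses it was 93% in both cell groups at a shift of 1, and unchanged genes made up 2.11% to 8.53% of the calls over the comparisons and shifts. The 1 raised list was called and none of 23 unchanged ones. Genes were simulated independently of each other, so this does not test the list calls where members vary together. Analyses ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.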

Results

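Transcript levels were measured on 8 Affymetrix arrays of primary human endometrial stromal cells, the connective tissue cells of the uterine lining that turn into decidual cells under progesterone. The cells received siRNA against REA (siREA), the repressor of estrogen receptor activity that the gene PHB2 encodes, or a control siRNA against luciferase (siGL3), a gene that human cells lack. They were then kept in 10 nM estradiol, 1 µM progesterone and 0.5 µM 8-bromo-cAMP, a cocktail that drives decidualization, for 24 h or 96 h. Each of the 4 groups held 2 arrays, 1 from each of 2 independent cultures from different donors, called culture 1 and culture 2. No culture without the hormone cocktail was among these samples.

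The number of arrays limits the precision of every value. Median intensity per array ran from 64.8 to 77.0, and 27.8% to 30.0% of the probe sets on an array lay under an intensity of 16. Across genes, which are not independent replicates, the arrays of a group correlated with Pearson r from 0.988 to 0.994. The first principal component held 44.9% of the variance and parted the 24 h arrays from the 96 h arrays. The second held 30.3% and parted siGL3 from siREA. The 3' to 5' ratio ran from 1.00 to 1.08 for GAPDH and from 1.96 to 2.80 for ACTB. In siGL3 cells the ACTB ratio was 2.20 and 2.46 at 24 h and 2.71 and 2.73 at 96 h, in cultures 1 and 2. In siREA cells it was 1.96 and 2.33 at 24 h and 2.01 and 2.80 at 96 h. The 18S ribosomal RNA probe set moved with the groups. Its intensity in siREA cells was 0.908 and 0.762 times that in siGL3 cells at 24 h, and 1.86 and 3.18 times at 96 h, in cultures 1 and 2.

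Whether the siRNA lowered its target was asked at both times. PHB2 intensity in siREA cells was 9.70% of that in siGL3 cells in culture 1 and 8.72% in culture 2 at 24 h, and 31.4% and 23.1% at 96 h. The log2 difference was -3.36 ± 0.14 at 24 h (SE, n = 2 per group, limma adjusted p = 1.39e-05) and -1.87 ± 0.14 at 96 h (adjusted p = 9.98e-05). The gap was smaller at 96 h by 1.49 ± 0.19 (limma adjusted p = 0.00477). PHB2 rose by 1.44 ± 0.14 from 24 h to 96 h in siREA cells (adjusted p = 0.000184) and differed by -0.05 ± 0.14 in siGL3 cells (adjusted p = 0.816). PHB1, whose product forms mitochondrial prohibitin complexes with REA, differed by 0.40 ± 0.14 at 24 h (adjusted p = 0.0796) and 0.18 ± 0.14 at 96 h (adjusted p = 0.401). The PHB1 rise at 24 h was called in 8 of 18 alternatives (adjusted p = 0.0217 to 0.421), among them quantile normalization and median centring. PHB1 was at 0.29 over both times, 0.37 from 24 h to 96 h in siGL3 cells, 0.15 in siREA cells and -0.21 in the interaction, not called in these (adjusted p = 0.0518, 0.0813, 0.461 and 0.594), while the first and second were each called in 6 alternatives.

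**Figure D1:**
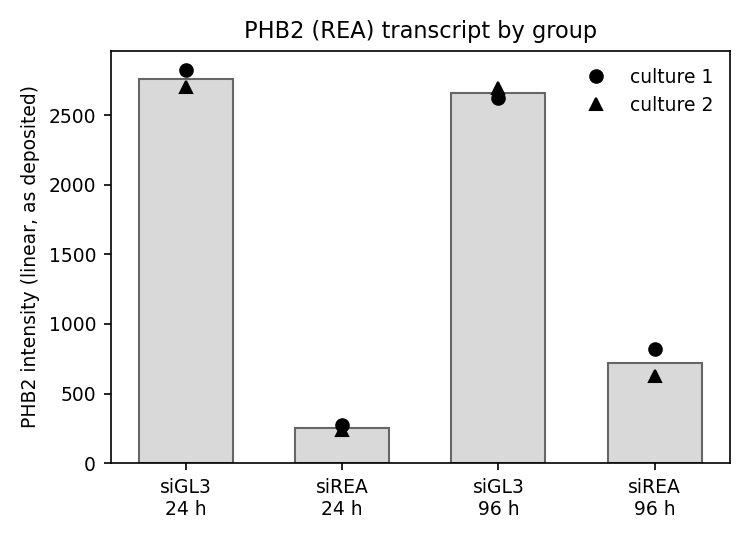
Linear PHB2 intensity on the vertical axis by group, with 1 symbol per culture and bars for the mean of 2 arrays. The 24 h siREA arrays read 274 and 236 against 2822 and 2702 in siGL3 cells, and the 96 h siREA arrays read 823 and 623 against 2626 and 2695.

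The comparison at 24 h asked which transcripts follow REA early under the hormone cocktail. PRL, the prolactin gene and a classic secreted product of decidual cells, fell by 1.73 ± 0.29 on the log2 scale in siREA cells (SE, n = 2 per group, limma adjusted p = 0.00460). BMP2, a morphogen that promotes decidualization, fell by 0.75 ± 0.13 (adjusted p = 0.00485). PGR, the progesterone receptor through which the hormone acts, rose by 1.40 ± 0.14 (adjusted p = 0.000577). By camera at the preset correlation the cell division and sterol synthesis lists rose and the inflammatory list fell, each with adjusted p = 0.825 with an estimated correlation, and fry called 0 lists at 24 h (6 at an unadjusted p under 0.05). IGFBP1, another decidual secretory product, differed by -0.49 ± 0.37 (adjusted p = 0.423) and WNT4 by 0.03 ± 0.22 (adjusted p = 0.950). IGFBP1 was called as lower in 3 of 18 alternatives, with only the arrays compared (adjusted p = 0.0146) and without either siREA 96 h array (0.0400), against up to 0.856 in the others. The decidual transcription factors FOXO1 and HAND2 differed by 0.13 ± 0.14 (adjusted p = 0.561) and 0.31 ± 0.16 (adjusted p = 0.218). ESR1, the estrogen receptor that REA was named for, differed by 0.15 ± 0.12 (adjusted p = 0.426). The PRL call ended without the culture term (adjusted p = 0.0816, with 1.42e-05 to 0.0816 over the alternatives) and the BMP2 call without the siGL3 24 h array of culture 2 (-0.65, adjusted p = 0.0710, with 0.00013 to 0.071 over the alternatives).

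The 12 genes with the largest rise at 24 h ran from PLSCR4, a phospholipid scramblase, at 2.60 ± 0.17 (limma adjusted p = 0.000131) to CYP1B1, a cytochrome P450 that hydroxylates estradiol, at 1.72 ± 0.18 (adjusted p = 0.000577). Between them rose GAS1, a cell surface protein of hedgehog signalling, by 2.28, LAMC1, a laminin chain, by 2.23, SST, the somatostatin gene, by 2.15, the kinase gene SIK1 by 2.13 and NPY1R, a neuropeptide Y receptor, by 1.93. AOX1, an aldehyde oxidase, rose by 1.87, TUFT1 by 1.78, the small GTPase gene RRAS2 by 1.78, TM4SF1 by 1.77 and SUCLG2, a mitochondrial succinyl-CoA ligase subunit, by 1.74. Among the genes with the largest fall, CACNA1G, a T-type calcium channel, fell by 3.55 ± 0.15 (adjusted p = 1.39e-05), CEMIP, a hyaluronan-binding protein, by 2.75, the metalloproteinase gene MMP11 by 2.64, the chemokine gene CXCL8 by 2.58 and the motor protein gene KIF5C by 2.56. GDF15, a stress-induced cytokine, fell by 2.47, the transcription factor gene DACH1 by 2.44, STC1, the stanniocalcin-1 gene, by 2.35, SYT1 by 2.32, HSD17B2, which oxidizes estradiol to estrone, by 2.26 and FRY by 2.24, with PHB2 itself among the 12. A group mean lay under an intensity of 16 for NPY1R in siGL3 cells and for CACNA1G and KIF5C in siREA cells, so the size of their change rests on the value added before the log. A second probe set of LAMC1 differed by -0.13 (adjusted p = 0.558) and one of MMP11 by 0.04 (adjusted p = 0.904).

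Of 34 measured cell division genes, 17 rose, 1 fell and 16 were not called at 24 h, and 25 rose and 2 fell adjusted over the list alone. The list median was 0.63 (camera adjusted p = 1.03e-08, adjusted p = 0.825 with an estimated correlation), with BIRC5, the survivin gene, up by 1.23, TOP2A by 0.97, BUB1B by 0.92 and KIF20A by 1.22. Of 15 genes of cholesterol synthesis, 6 rose, none fell and 9 were not called, and 7 rose adjusted over the list alone. The cholesterol list had a median of 0.40 (camera adjusted p = 2.74e-05, adjusted p = 0.825 with an estimated correlation), among them INSIG1 by 1.40, HMGCS1 by 1.28 and MSMO1 by 0.96. Of 17 endoplasmic reticulum chaperone genes, 5 rose, 1 fell and 11 were not called, and 8 rose and 1 fell adjusted over the list alone. For the chaperone list the median was 0.31 (camera adjusted p = 0.000697, adjusted p = 0.825 with an estimated correlation), led by MANF at 1.35 and HYOU1 at 0.60. Of 11 progestin response genes, 4 rose and 7 were not called, and 6 rose adjusted over the list alone. The progestin list stood at a median of 0.41 (camera adjusted p = 0.00694, adjusted p = 0.825 with an estimated correlation), namely SGK1 by 0.76, CEBPD by 0.77, DUSP1 by 0.73 and KLF9 by 0.41. Of 20 inflammatory genes, 8 fell and 12 were not called, and 8 fell adjusted over the list alone. The inflammatory list had a median of -0.48 (camera adjusted p = 0.0244, adjusted p = 0.825 with an estimated correlation), with IL11 down by 0.93, LIF down by 1.28 and PTGS2, the inducible cyclooxygenase gene, down by 1.41. The decidual markers went both ways. Of 23 measured, 6 rose, 2 fell and 15 were not called, the same 6 and 2 adjusted over the list alone. For the decidual list the median was 0.22 (camera adjusted p = 0.0245, adjusted p = 0.825 with an estimated correlation), with SST at 2.15 and TIMP3 at 1.59 up and PRL and BMP2 down. The decidual list call ended in 6 of 17 alternatives, with adjusted p up to 0.137. They were quantile normalization, median centring, the fit without the culture term, the lowest 50% left out, 64 added before the log and the fit without the siGL3 24 h array of culture 2. The inflammatory list call ended without the siGL3 24 h array of culture 1 or the siREA 24 h array of culture 2, with the lowest 50% left out and with 64 added, with adjusted p up to 0.29 over the alternatives.

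Of 9523 genes tested with limma at 24 h, 634 rose and 1063 fell, and 114 of the rises and 221 of the falls were at least 2-fold. The 37.4% of calls that were rises became 49.5% of 1934 calls after quantile normalization and 57.1% of 1865 calls with arrays centred on their medians. Centring moved the median difference of all genes from -0.05 to 0.06, so list medians at 24 h stand against an all-gene median of -0.05. The total of 1697 calls was 622 without the siGL3 24 h array of culture 1, 805 without that of culture 2, 872 without the siREA 24 h array of culture 1 and 839 without that of culture 2.

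The comparison at 96 h asked the same after longer exposure to the hormone cocktail. Most decidual markers were higher in siREA cells. MAOB and MAOA, the monoamine oxidase genes, rose by 3.19 ± 0.18 and 2.71 ± 0.18 (SE, n = 2 per group, limma adjusted p = 2.99e-05 and 5.71e-05). WNT4, a signal needed for decidualization, rose by 2.32 ± 0.22 (adjusted p = 0.000286) and HAND2 by 1.04 ± 0.16 (adjusted p = 0.00256). PRL rose by 0.97 ± 0.29 (adjusted p = 0.0460) and IGFBP1 by 1.43 ± 0.37 (adjusted p = 0.0285), with most of the rise in culture 2, where they differed by 1.64 and 2.33 against 0.30 and 0.53 in culture 1. Of 20 inflammatory genes 16 were lower, with CXCL1, a neutrophil chemokine, down 55.8-fold at -5.80 ± 0.46 (adjusted p = 0.000143). FOXO1 rose by 0.52 ± 0.14 (adjusted p = 0.0286), PGR by 0.94 ± 0.14 (adjusted p = 0.00293) and ESR1 by 0.62 ± 0.12 (adjusted p = 0.00646), and BMP2 fell by 0.62 ± 0.13 (adjusted p = 0.0109). The other probe sets of ESR1 differed by -0.07 and 0.25 and were not called. That of BMP2 differed by -0.48 and was not called either (limma adjusted p = 0.0566). PRL was called in 8 of 18 alternatives and IGFBP1 in 12 of 18 (adjusted p = 1.11e-05 to 0.301 and 8.19e-12 to 0.223). The PRL difference was 0.34 without the siGL3 96 h array of culture 2, 0.71 without the siREA 96 h array of culture 2 and 1.24 without that of culture 1, not called in these. It was 1.60 and called without the siGL3 96 h array of culture 1. Its call also ended without either siREA 24 h array, which leaves the difference as it is (adjusted p = 0.0664), under quantile normalization and under median centring, with no filter and with 1 added. The IGFBP1 difference was 0.58 without the siREA 96 h array of culture 2 and 1.08 without the siGL3 96 h array of culture 2, not called in either, and 2.28 without the siREA 96 h array of culture 1. The IGFBP1 call also ended under quantile normalization, under median centring and with 1 added. The FOXO1 call ended without the siREA 96 h array of culture 2 (0.38) or culture 1 (0.65) or the siGL3 96 h array of culture 2 (0.40) and with 1 added. The ESR1 call ended without the siREA 96 h array of culture 1 (0.60) and the BMP2 call without that of culture 2 (-0.51). The calls of PRL, IGFBP1, FOXO1, ESR1 and BMP2 also ended without the culture term (adjusted p = 0.301, 0.191, 0.0998, 0.279 and 0.0575), with highest values over the alternatives of 0.301, 0.223, 0.207, 0.279 and 0.0991.

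**Figure D2:**
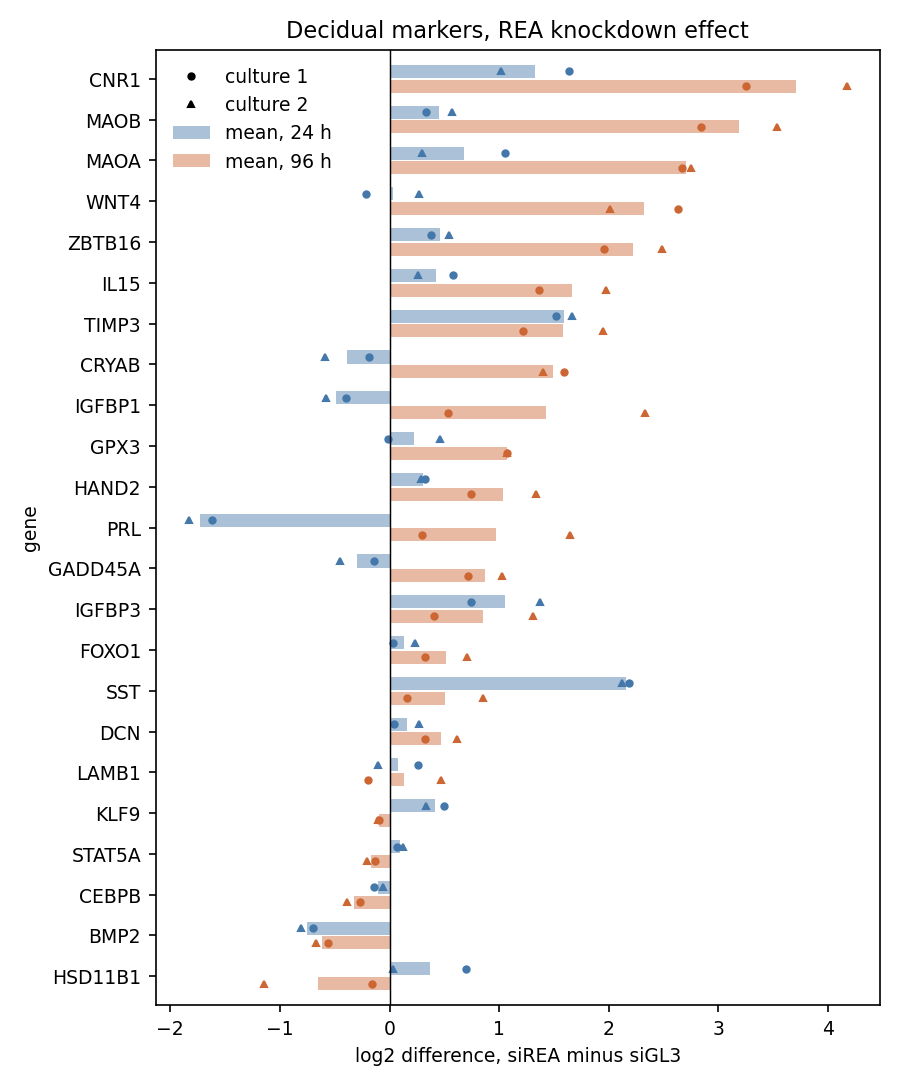
Log2 difference between siREA and siGL3 cells on the horizontal axis for the 23 measured decidual markers, with bars for the mean of 2 cultures at 24 h and 96 h and symbols for each culture. PRL lies at -1.73 at 24 h and 0.97 at 96 h, and CNR1 reaches 3.71 at 96 h.

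The largest rise at 96 h was that of CNR1, the cannabinoid receptor 1 gene, at 3.71 ± 0.30 (limma adjusted p = 0.000161). THSD7A rose by 2.95, the testis chaperone gene CLGN by 2.89, ENPP1, an ectonucleotide pyrophosphatase, by 2.85 and the matrix protein gene MATN2 by 2.84. The sulfotransferase gene CHST7 rose by 2.84, KCTD12 by 2.78, BCHE, the butyrylcholinesterase gene, by 2.77, the chemokine scavenger gene ACKR3 by 2.66 and IGF1, an insulin-like growth factor, by 2.60. After CXCL1, the largest falls were those of RGS5, a regulator of G-protein signalling, by 5.34 ± 0.71 (adjusted p = 0.00151), CX3CL1, the fractalkine gene, by 5.02, IL24 by 4.85, and the chemokine genes CXCL2 by 4.78, CXCL3 by 4.40 and CXCL5 by 4.29. C3, complement component 3, fell by 4.11, CHI3L1 by 3.86, GDF15 by 3.81, TNFSF4, the OX40 ligand gene, by 3.71 and PTGS2 by 3.52. Group means lay under an intensity of 16 for CNR1 and WNT4 in siGL3 cells and for RGS5, CX3CL1 and CXCL3 in siREA cells. The THSD7A difference was 1.80 without the siGL3 96 h array of culture 2, and 2.19 and not called without the siREA 96 h array of culture 2 (adjusted p = 0.0579, with values up to 0.0765 over the alternatives).

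Of 20 measured inflammatory genes, 16 fell, none rose and 4 were not called at 96 h, and 18 fell adjusted over the list alone. Their median was -2.81 (camera adjusted p = 1.16e-14, adjusted p = 0.491 with an estimated correlation), at -2.41 in culture 1 and -2.75 in culture 2, with CXCL3, CXCL6 at -3.21, PTGS2 and CXCL2 leading. The 18S ribosomal RNA signal was higher in siREA cells at this time, while these genes fell. Of 23 decidual markers, 15 rose, 1 fell and 7 were not called, and 16 rose and 2 fell adjusted over the list alone. The decidual list stood at a median of 0.97 (camera adjusted p = 2.55e-07, adjusted p = 0.491 with an estimated correlation), among them ZBTB16, a progestin-induced transcription factor gene, at 2.22. The median absolute difference of its members was 0.56 in culture 1 and 1.31 in culture 2. Of 17 endoplasmic reticulum chaperone genes, 9 rose, 1 fell and 7 were not called, and 11 rose and 1 fell adjusted over the list alone. The chaperone list had a median of 0.44 (camera adjusted p = 5.63e-05, adjusted p = 0.491 with an estimated correlation), with MANF at 1.15, HERPUD1 at 0.82, CRELD2 at 0.75 and PDIA6 at 0.78. Of 13 p53 target genes, 8 fell, 1 rose and 4 were not called, and 9 fell and 1 rose adjusted over the list alone. For the p53 list the median was -0.60 (camera adjusted p = 0.00311, adjusted p = 0.768 with an estimated correlation), including the death receptor gene FAS at -1.19, ZMAT3 at -1.16 and CDKN1A, a cell cycle inhibitor, at -1.02. Of 18 hypoxia and glycolysis genes, 6 fell and 12 were not called, and 10 fell adjusted over the list alone. The hypoxia list stood at a median of -0.39 (camera adjusted p = 0.00173, adjusted p = 0.491 with an estimated correlation), led by the adrenomedullin gene ADM at -1.75 and the hexokinase gene HK2 at -1.13. Of 34 cell division genes, 8 rose, 4 fell and 22 were not called, and 13 rose and 4 fell adjusted over the list alone. The cell division list had a median of 0.26 (camera adjusted p = 0.0213, adjusted p = 0.768 with an estimated correlation). TOP2A at 1.02 and BIRC5 at 1.02, which act in mitosis, were up, and TYMS at -1.73 and PCNA at -0.78, which act in DNA synthesis, were down. Of 9 stromal markers, 3 rose, 1 fell and 5 were not called, the same 3 and 1 adjusted over the list alone. For the stromal list the median was 0.37 (camera adjusted p = 0.0213, adjusted p = 0.629 with an estimated correlation), with MME at 1.51 up and PDGFRB at -0.73 down. With fry, which tests each list on its own, the decidual, chaperone, inflammatory, hypoxia and stromal lists passed at 96 h (adjusted p = 0.0227, 0.0218, 0.0268, 0.0218 and 0.0493). The cell division list call ended without the siGL3 96 h array of culture 2 or the siREA 96 h array of culture 1, under median centring, with the lowest 50% left out and with 64 added (adjusted p up to 0.645 over the alternatives). The stromal call ended without the siGL3 96 h array of culture 2, under quantile normalization and under median centring (up to 0.153).

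**Figure D3:**
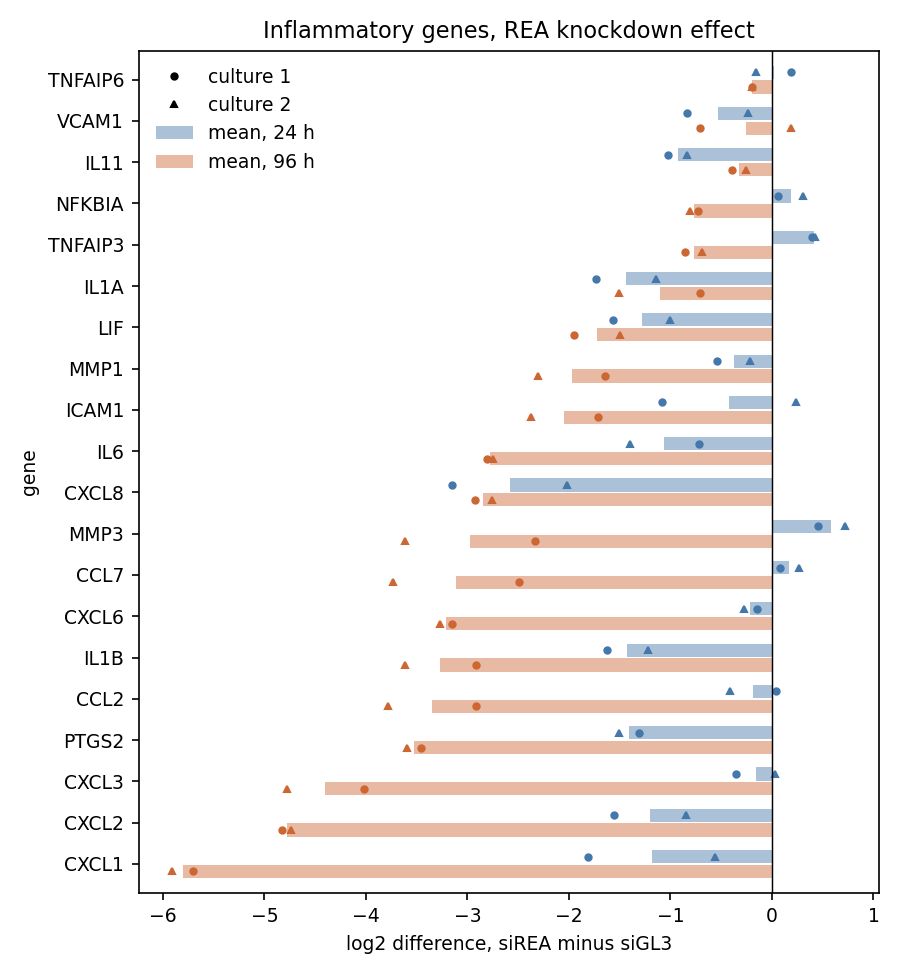
Log2 difference between siREA and siGL3 cells on the horizontal axis for the 20 measured inflammatory genes, with bars for the mean of 2 cultures at 24 h and 96 h and symbols for each culture. CXCL1 lies at -5.80 at 96 h, and the list median is -0.48 at 24 h and -2.81 at 96 h.

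Of 9523 genes tested with limma at 96 h, 932 rose and 983 fell, and 199 of the rises and 246 of the falls were at least 2-fold. The total of 1915 calls was 911 without the siREA 96 h array of culture 2, 943 without that of culture 1 and 920 without the siGL3 96 h array of culture 2. The majority turned to rising genes under median centring (1045 rising, 992 falling), with 1 added (713 and 698), with every probe set (1050 and 1031) and without the siREA 96 h array (471 and 440) or the siGL3 96 h array (502 and 418) of culture 2. Without the siGL3 96 h array of culture 1 there were 711 rising and 1114 falling.

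Averaged over both times, with 4 arrays against 4, knockdown raised CNR1 by 2.52 ± 0.21 (SE, limma adjusted p = 0.000107) and lowered CXCL1 by 3.49 (adjusted p = 0.000163), and this comparison asked for the mean effect, which can come from 1 time alone. GAS1 rose by 2.27, TM4SF1 by 2.14, ACKR3 by 2.13, CLGN by 2.05, ID4, an inhibitor of DNA binding, by 1.99, SIK1 by 1.95, PLSCR4 by 1.95, BCHE by 1.90, KCTD12 by 1.88, MAOB by 1.82 and MAMLD1 by 1.75. Next to CXCL1, the gene IL24 fell by 3.32, CX3CL1 by 3.20, GDF15 by 3.14, RGS5 by 3.03, CXCL2 by 2.99, TNFSF4 by 2.92, CXCL8 by 2.71, PHB2 by 2.62, CHI3L1 by 2.49, PTGS2 by 2.47, and ACKR4, a chemokine scavenger, was at -2.39. PGR rose by 1.17 ± 0.10 (adjusted p = 0.000127), while PRL, at -1.73 at 24 h and 0.97 at 96 h, averaged -0.38 ± 0.20 (adjusted p = 0.206). Without the siGL3 96 h array of culture 2 PRL averaged -0.69 and was called (adjusted p = 0.00350), and over the other alternatives adjusted p ran up to 0.652. WNT4 rose by 1.17, HAND2 by 0.67, ESR1 by 0.39 and FOXO1 by 0.32, and BMP2 fell by 0.69 (adjusted p = 0.000807, 0.00230, 0.00784, 0.0330 and 0.000839). The other probe sets of ESR1 were at -0.17 and 0.07 and were not called (adjusted p = 0.281 and 0.612). The FOXO1 call was kept in 9 of 17 alternatives (adjusted p up to 0.158). It ended without the culture term, with 1 added, and without any of the 24 h arrays or either 96 h array of culture 2. The ESR1 call ended without the culture term and without the siGL3 24 h array of culture 1 (adjusted p up to 0.301). IGFBP1 differed by 0.47 ± 0.26 (adjusted p = 0.224), and by 0.90, called, without the siREA 96 h array of culture 1 (0.00144 to 0.801 over the alternatives).

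Of 9523 genes, limma called 1162 as higher and 1619 as lower in siREA cells over both times, with 94 and 185 of them at least 2-fold. Of the 2781, 2354 had the same sign in both cultures at both times, and in the other comparisons all called genes had the same sign in both cultures. The 41.8% of calls that were rises became 49.5% of 3182 calls after quantile normalization and 54.7% of 3065 with arrays centred on their medians, and the total of 2781 was 1751 without the siGL3 24 h array of culture 1. Called at both times were 279 genes that rose at both times and 429 that fell at both, where independent draws would give 62.05 and 109.7, against 14 that rose and then fell and 39 that fell and then rose.

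Over both times 7 lists were called, each with adjusted p = 0.663 with an estimated correlation. Of 23 decidual markers 13 rose, 1 fell and 9 were not called, with 15 and 1 adjusted over the list alone (median 0.55, camera adjusted p = 3.64e-06), and MAOA at 1.69 and TIMP3 at 1.59 were among them. Of 34 cell division genes 20 rose, 4 fell and 10 were not called, with 21 and 4 adjusted over the list alone (median 0.47, adjusted p = 6.02e-06), including BIRC5 at 1.12 and TYMS at -1.34. Of 17 chaperone genes 10 rose, 1 fell and 6 were not called, with 12 and 1 adjusted over the list alone (median 0.38, adjusted p = 1.72e-05), including MANF at 1.25 and HERPUD1 at 0.68. Of 20 inflammatory genes 16 fell and 4 were not called, with 17 down adjusted over the list alone (median -1.49, adjusted p = 4.25e-10), including CXCL3 at -2.28 and CXCL6 at -1.71. Of 15 cholesterol synthesis genes 5 rose and 10 were not called, also 5 adjusted over the list alone (median 0.18, adjusted p = 0.00513), including INSIG1 at 0.91 and HMGCS1 at 0.86. Of 11 progestin response genes 6 rose and 5 were not called, also 6 adjusted over the list alone (median 0.34, adjusted p = 0.0108), including ZBTB16 at 1.34 and CDKN1C at 0.81. Of 13 p53 targets 8 fell, 1 rose and 4 were not called, with 10 and 2 adjusted over the list alone (median -0.36, adjusted p = 0.00770), including FAS at -1.28 and BAX at -0.53. The cell division and progestin calls ended with the lowest 50% left out (adjusted p up to 0.0754 and 0.0718 over the alternatives).

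For 8 lists camera made no call in any of the 6 comparisons, and their results over both times were as follows. Of 15 estrogen response genes 3 rose and 2 fell, also 3 and 2 adjusted over the list alone (median -0.03, mean 0.04, adjusted p = 0.710), with CCND1, the cyclin D1 gene, at -1.15 and STC2 at -1.35. Of 15 steroid receptors and coregulators 3 rose and 3 fell, with 6 and 3 adjusted over the list alone (median -0.01, mean 0.03, adjusted p = 0.551), with PGR up and NR2F1 at -1.35. Of 17 mitochondrial chaperones and proteases 3 fell, also 3 adjusted over the list alone (median -0.10, adjusted p = 0.433), with CLPP, a matrix protease gene, at -0.47 and TOMM20 at -0.32. Of 27 interferon response genes 2 rose and 6 fell, the same adjusted over the list alone (median -0.10, adjusted p = 0.267), with TRIM22 at -0.57 and IFIT1 at -0.55. Of 29 extracellular matrix genes 4 rose and 10 fell, with 4 and 11 adjusted over the list alone (median -0.04, adjusted p = 0.551), with LAMC1 at 1.38, LAMA4 at 0.96, the biglycan gene BGN at -1.20 and COL8A1 at -1.26. Of 9 epithelial markers 2 fell, KRT19 at -0.67 and KRT18 at -0.63 (median -0.22, adjusted p = 0.190). Of 6 leukocyte markers GNLY rose at 0.28 and CD74 fell at -0.81 (median 0.23, adjusted p = 0.240). Of 10 smooth muscle and pericyte markers 2 rose and 2 fell, with ABCC9 at 1.10 and RGS5 at -3.03 (median 0.02, mean -0.22, adjusted p = 0.741). The endothelial list, called over time only, was not called in the knockdown comparisons. Its medians there were -0.41 at 24 h, -0.61 at 96 h and -0.76 over both times (camera adjusted p = 0.380, 0.209 and 0.147). Of its 5 markers 2 fell at 24 h, TEK at -0.59 and KDR at -0.92, 1 at 96 h, ENG at -1.15, and these 3 over both times. Camera did not call the cAMP, respiratory chain, integrated stress response, contractile, hypoxia, BMP, proteasome and stromal lists over both times either (adjusted p from 0.0669 to 0.908). With fry the hypoxia list was called as lower and the leukocyte list as higher over both times (adjusted p = 0.0259 each), and the cholesterol list was not called (adjusted p = 0.0889).

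**Figure D4:**
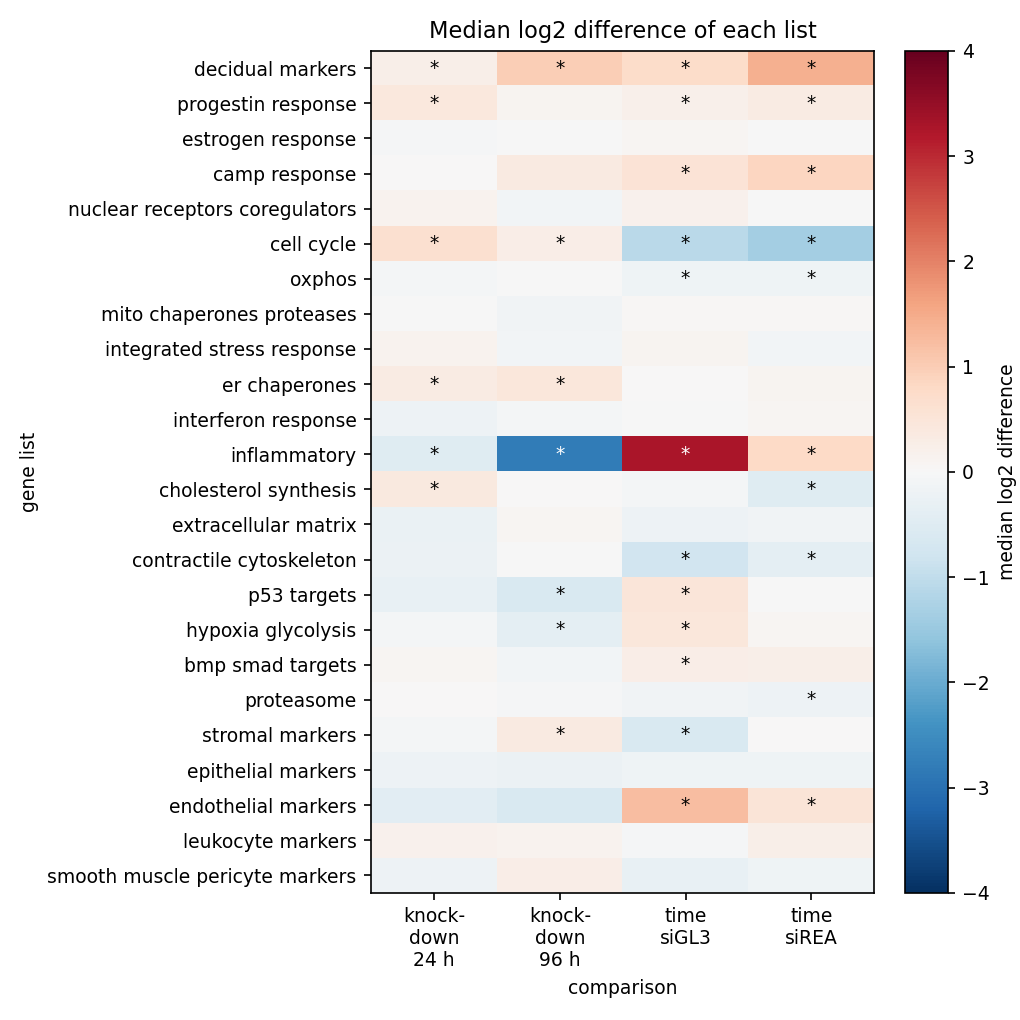
Median log2 difference of each gene list, as colour, for knockdown at 24 h and 96 h and for the change from 24 h to 96 h in siGL3 and siREA cells, with a star where the camera adjusted p was under 0.05. The inflammatory list has medians of -0.48, -2.81, 3.27 and 0.81 from left to right.

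Whether the effect of knockdown differed between the times was tested as an interaction, the effect at 96 h minus that at 24 h. Gains, losses, higher and lower are meant with the sign, so a fall that was larger at 96 h counts as a loss. The PRL effect was -1.73 at 24 h and 0.97 at 96 h. Its difference was 2.70 ± 0.41 (SE, n = 2 per group, limma adjusted p = 0.00936). The PRL effect at 96 h lay mostly in culture 2 and was 0.34 without the siGL3 96 h array of culture 2. WNT4 differed by 2.29 ± 0.31 (adjusted p = 0.00528). The WNT4 call ended without the culture term (adjusted p = 0.0889, the highest over the alternatives, which ran from 0.000225) and with 1 added. IGFBP1 differed by 1.92 ± 0.53 (adjusted p = 0.0707) and HAND2 by 0.73 ± 0.22 (adjusted p = 0.0904), neither called. With other settings IGFBP1 was called in 5 of 17 alternatives, among them the fits without the siREA 96 h array of culture 2 (1.07) and of culture 1 (2.77), and HAND2 in 4 of 17, among them that without the siGL3 96 h array of culture 1 (0.98). FOXO1 at 0.38, PGR at -0.46, ESR1 at 0.47 and BMP2 at 0.14 were not called either (adjusted p = 0.297, 0.240, 0.135 and 0.742). The largest gains at 96 h were those of MATN2 at 4.48 ± 0.56 (adjusted p = 0.00403), the semaphorin receptor gene PLXNC1 at 3.39, THSD7A at 3.38, the proteoglycan gene EPYC at 3.34, MGP, the matrix Gla protein gene, at 3.26 and IGF1 at 2.98. They were followed by SFRP4, a secreted Wnt antagonist, at 2.83, MMP10 at 2.76, ENPP1 at 2.74, MAOB at 2.74 and the amino acid transporter gene SLC7A8 at 2.49. The largest losses were those of CXCL5 at -4.70 ± 0.39 (adjusted p = 0.00122), RGS5 at -4.62, CXCL1 at -4.62, CXCL3 at -4.24 and C3 at -4.15. Next were CX3CL1 at -3.64, CXCL2 at -3.58, the stromelysin gene MMP3 at -3.56, CCL7 at -3.28, CCL2 at -3.16, CXCL6 at -3.00 and RGS4 at -2.66. Group means under an intensity of 16 enter the values of THSD7A, SFRP4, RGS5, CXCL1, CXCL2, CXCL3, CXCL6, C3, CX3CL1 and WNT4. The PRL call ended without the siREA 24 h array of culture 1 (2.59, adjusted p = 0.0566) and without the culture term (adjusted p = 0.124, the highest over the alternatives, which ran from 9.75e-05). The RGS5, THSD7A and CX3CL1 calls were kept in 9 of 17, 9 of 16 and 7 of 17 alternatives (adjusted p up to 0.14, 0.156 and 0.174), and each ended without the culture term, under quantile normalization, under median centring and with 1 added. CX3CL1 was also not called with no filter. The calls of CCL7, RGS4, PLXNC1, IGF1, CXCL1, CXCL2, CCL2 and MGP ended with 1 added, and that of MGP also without the culture term. The RGS5 call ended without the siREA 24 h array of culture 1 (-4.12) or culture 2 (-5.12) or the siREA 96 h array of culture 2 (-4.01) or culture 1 (-5.22), and RGS5 was -2.93 without the siGL3 96 h array of culture 2. The CX3CL1 call ended without the siREA 24 h array of culture 1 (-2.94) or culture 2 (-4.35), the siREA 96 h array of culture 2 (-2.78) or the siGL3 96 h array of culture 2 (-3.15) or culture 1 (-4.14). The THSD7A call ended without the siREA 24 h array of culture 1 (2.97) or culture 2 (3.79) or the siREA 96 h array of culture 2 (2.62), and THSD7A was 2.23 without the siGL3 96 h array of culture 2. The CCL7 call ended without the siREA 24 h array of culture 1 (-2.90) or the siREA 96 h array of culture 2 (-3.32) or culture 1 (-3.25). The RGS4 call ended without the siREA 24 h array of culture 1 (-2.38) or the siREA 96 h array of culture 2 (-2.62).

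**Figure D5:**
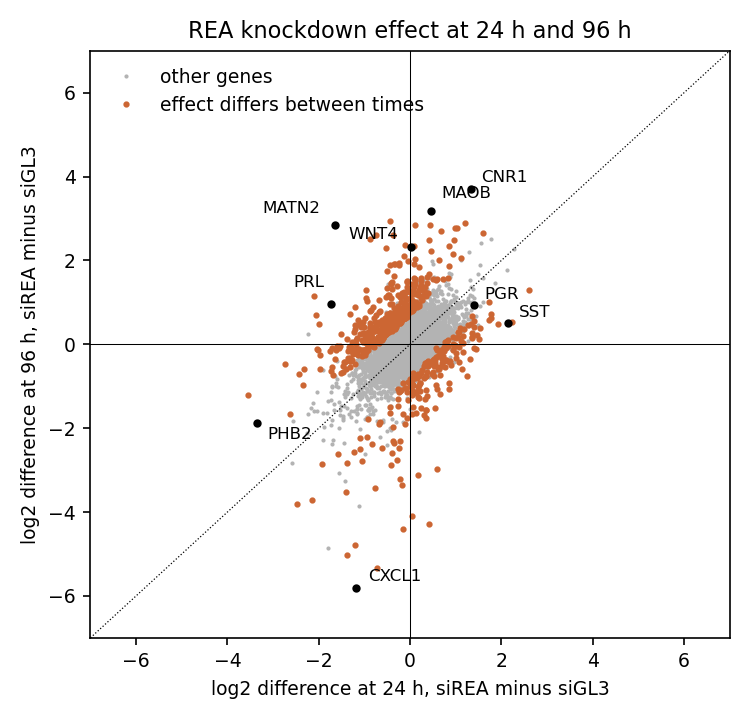
Log2 difference between siREA and siGL3 cells at 24 h on the horizontal axis and at 96 h on the vertical axis, 1 point per gene, with genes whose effect differed between the times in orange and equal effects on the dotted line. PRL lies at -1.73 and 0.97, and CXCL1 at -1.19 and -5.80.

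In the interaction, 9 of 23 decidual markers had a higher knockdown effect at 96 h, 1 a lower one and 13 were not called, with 11 and 2 adjusted over the list alone. The decidual list stood at a median of 0.73 (camera adjusted p = 0.000568, adjusted p = 0.839 with an estimated correlation), and MAOA at 2.03 and CRYAB, a small heat shock protein gene, at 1.88 were among them. Of 20 inflammatory genes 11 had a lower effect and 9 were not called, with 14 lower and 1 higher adjusted over the list alone. The inflammatory list had a median of -1.67 (camera adjusted p = 2.63e-11, adjusted p = 0.839 with an estimated correlation), with CXCL3 at -4.24 and MMP3 at -3.56. Of 15 cholesterol synthesis genes 3 had a lower effect and 12 were not called, with 4 lower adjusted over the list alone. For the cholesterol list the median was -0.44 (camera adjusted p = 0.000309, adjusted p = 0.888 with an estimated correlation), namely INSIG1 at -0.99, MSMO1 at -1.02 and SREBF2 at -0.87. Of 34 cell division genes none was called singly or adjusted over the list alone, while the list had a lower effect at 96 h. The cell division list stood at a median of -0.37 (camera adjusted p = 0.000199, adjusted p = 0.839 with an estimated correlation). Of 18 hypoxia and glycolysis genes only ADM was called, at -2.09, also adjusted over the list alone. The hypoxia list had a median of -0.25 (camera adjusted p = 0.000937, adjusted p = 0.839 with an estimated correlation). Of 20 integrated stress response genes VLDLR had a higher effect at 0.78 and GDF15 a lower one at -1.34, with 1 higher and 2 lower adjusted over the list alone. For the stress response list the median was -0.24 (camera adjusted p = 0.0263, adjusted p = 0.888 with an estimated correlation). Of 9 stromal markers none was called over all genes, and 3 were higher and 1 lower adjusted over the list alone. The stromal list stood at a median of 0.45 (camera adjusted p = 0.0413, adjusted p = 0.839 with an estimated correlation). The p53 target, progestin response and endoplasmic reticulum chaperone lists were not called in the interaction (medians -0.32, -0.11 and 0.12, adjusted p = 0.0982, 0.485 and 0.485). The calls of the p53 list at 96 h alone and of the progestin list at 24 h alone do not show a difference between the times. The integrated stress response call ended without either 96 h array of culture 2, under quantile normalization and median centring, with the lowest 50% left out and with 1 added (adjusted p up to 0.141 over the alternatives). The stromal call ended without any of the 24 h or 96 h arrays of culture 2 or the siREA 24 h array of culture 1, without the culture term, under quantile normalization and median centring and with 1 added (up to 0.260). The cell division call ended with 1 added (up to 0.106).

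The interaction called 594 of 9523 genes, 398 with a higher and 196 with a lower effect at 96 h. The total was 191 without the culture term, 160 with 1 added, 1033 with an intensity trend and 966 with 64 added. Of them 192 were called at 24 h only, 275 at 96 h only, 112 at both times and 15 at neither, and among the 112 the effect had opposite signs in 53, was smaller at 96 h in 28 and larger in 31. The 67.0% of calls with a higher effect became 55.1% of 595 after quantile normalization and 48.3% of 528 with arrays centred on their medians. The total was 312 and 224 without the siGL3 24 h array of culture 1 and culture 2, 176 and 280 without the siREA 24 h array of culture 1 and culture 2. It was 259 and 246 without the siREA 96 h array of culture 1 and culture 2 and 277 without the siGL3 96 h array of culture 2.

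In siGL3 cells the change from 24 h to 96 h was measured under the hormone cocktail alone, so differentiation, time in culture and time after transfection are not separated. IGFBP1 rose by 2.87 ± 0.37 (SE, n = 2 per group, limma adjusted p = 0.000946), BMP2 by 2.20 ± 0.13 (adjusted p = 2.49e-05), PRL by 1.47 ± 0.29 (adjusted p = 0.00691) and FOXO1 by 1.05 ± 0.14 (adjusted p = 0.000893). The other probe set of FOXO1 was at 0.54 and not called (limma adjusted p = 0.0523). By camera at the preset correlation the inflammatory and decidual lists rose and the cell division list fell, each with adjusted p = 0.305 with an estimated correlation. WNT4 differed by -0.54 ± 0.22 (adjusted p = 0.107), and HAND2, PGR and ESR1 were at 0.07, 0.29 and 0.32, not called. WNT4 was called without the siGL3 24 h (-0.87) or 96 h (-0.92) array of culture 2, and ESR1 under quantile normalization (adjusted p = 0.0410, with 0.0410 to 0.569 over the alternatives). The largest rises were those of CXCL1 at 5.97 ± 0.46 (adjusted p = 7.91e-05), SST at 5.84, IL13RA2, an interleukin-13 decoy receptor, at 5.37, IL1B, the interleukin-1 beta gene, at 5.25, and C3 at 4.89. They were followed by the chemokine receptor gene CXCR4 at 4.55, CXCL2 at 4.45, CXCL5 at 4.26, RGS5 at 4.25, PIP5K1B at 4.12, CXCL3 at 4.11 and CXCL8 at 4.05. The largest falls were those of TNC, the tenascin C gene, at -3.26 ± 0.17 (adjusted p = 1.66e-05), S100A10 at -3.01, the potassium channel gene KCNMA1 at -2.97 and MATN2 at -2.86. Next came IGF2BP3 at -2.82, the mitotic kinesin gene KIF20A at -2.72, CHN1 at -2.68, ITGBL1 at -2.43, ADH1B at -2.42, the calponin gene CNN1 at -2.41, PRUNE2 at -2.41 and MXRA5 at -2.41. Group means lay under an intensity of 16 for C3, PIP5K1B and CXCL3 at 24 h and for KIF20A at 96 h. The PRL difference was 0.84 without the siGL3 96 h array of culture 1 and its call ended without the culture term (adjusted p = 0.105, with 0.000224 to 0.105 over the alternatives). The RGS5 difference was 2.56 without the siGL3 96 h array of culture 2.

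In siGL3 cells 17 of 20 inflammatory genes rose with time and 3 were not called, with 18 up adjusted over the list alone. The inflammatory list had a median of 3.27 (camera adjusted p = 1.15e-15, adjusted p = 0.305 with an estimated correlation), including IL11 at 3.36, CXCL6 at 3.75 and IL6 at 3.47. The 18S ribosomal RNA signal moved the other way, from 7197 and 8662 at 24 h to 1322 and 1991 at 96 h in cultures 1 and 2. Of 23 decidual markers 13 rose, 1 fell and 9 were not called, with 15 and 2 adjusted over the list alone. For the decidual list the median was 0.75 (camera adjusted p = 1.22e-06, adjusted p = 0.305 with an estimated correlation), with TIMP3 at 1.42 and KLF9 at 0.95 up and CRYAB at -0.83 down. Of 15 cAMP response genes 7 rose and 8 were not called, also 7 adjusted over the list alone. The cAMP list stood at a median of 0.54 (camera adjusted p = 9.28e-06, adjusted p = 0.431 with an estimated correlation), with the phosphodiesterase gene PDE4B at 1.84 and SIK1 at 1.83. Of 34 cell division genes 23 fell, 1 rose and 10 were not called, with 24 and 1 adjusted over the list alone. The cell division list had a median of -1.07 (camera adjusted p = 1.21e-09, adjusted p = 0.305 with an estimated correlation), led by BIRC5 at -2.29 and CCNB2 at -1.86. Of 18 hypoxia and glycolysis genes 9 rose and 9 were not called, with 13 up adjusted over the list alone. For the hypoxia list the median was 0.44 (camera adjusted p = 2.10e-05, adjusted p = 0.305 with an estimated correlation), led by ADM at 2.05. Of 13 p53 targets 7 rose, 1 fell and 5 were not called, also 7 and 1 adjusted over the list alone. The p53 list stood at a median of 0.48 (camera adjusted p = 0.00468, adjusted p = 0.698 with an estimated correlation), led by MDM2 at 1.33. Of 11 BMP and SMAD targets 4 rose and 7 were not called, also 4 adjusted over the list alone. The BMP list had a median of 0.27 (camera adjusted p = 0.00802, adjusted p = 0.305 with an estimated correlation), led by BAMBI at 1.68. Of 11 progestin response genes 5 rose and 6 were not called, also 5 adjusted over the list alone. For the progestin list the median was 0.19 (camera adjusted p = 0.0107, adjusted p = 0.668 with an estimated correlation), with DUSP1 at 1.29 and SGK1 at 0.97. Of 16 contractile cytoskeleton genes 9 fell, 3 rose and 4 were not called, the same adjusted over the list alone. The contractile list stood at a median of -0.77 (camera adjusted p = 0.0177, adjusted p = 0.756 with an estimated correlation), with CNN1 down and CCN2, a growth factor-induced matricellular gene, up at 2.83. Of 55 respiratory chain subunits 7 fell and 48 were not called, with 3 down adjusted over the list alone. The respiratory chain list had a median of -0.18 (camera adjusted p = 0.0107, adjusted p = 0.816 with an estimated correlation), with NDUFA10 at -0.74 and NDUFB5 at -0.50. Of 9 stromal markers 5 fell, 1 rose and 3 were not called, the same adjusted over the list alone. For the stromal list the median was -0.59 (camera adjusted p = 0.0436, adjusted p = 0.546 with an estimated correlation), with MME at -1.65 and NT5E at -0.76 down and PDGFRB at 0.82 up. Of 5 endothelial markers 3 rose and 2 were not called, also 3 adjusted over the list alone. The endothelial list stood at a median of 1.24 (camera adjusted p = 0.00396, adjusted p = 0.305 with an estimated correlation), with KDR, the receptor for vascular endothelial growth factor, at 2.51. Without the siGL3 96 h array of culture 1 the progestin, contractile, BMP and respiratory chain list calls ended (adjusted p up to 0.0644, 0.0571, 0.0571 and 0.155 over the alternatives). The respiratory chain call also ended without the siGL3 24 h array of culture 1. The stromal call was kept in 8 of 17 alternatives (up to 0.279). It ended without the siGL3 24 h or 96 h array of culture 2 or either siREA 24 h array, without the culture term, with only the arrays compared, under quantile normalization and median centring and with 1 added. With fry the respiratory chain, contractile and p53 lists were not called for time in siGL3 cells (adjusted p = 0.159, 0.133 and 0.101), and the extracellular matrix list was called as lower (adjusted p = 0.0246).

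In siGL3 cells limma called 1017 of 9523 genes as rising and 1337 as falling with time, 288 and 274 of them at least 2-fold. Which direction held more calls depended on the scaling: median centring gave 1320 rising and 1203 falling, and quantile normalization 1244 and 1430. Without the siGL3 96 h array of culture 1 there were 1091 rising and 934 falling. The total of 2354 was 1150 and 1015 without the siGL3 24 h array of culture 1 and culture 2 and 1534 without the siGL3 96 h array of culture 2.

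In siREA cells decidual genes rose over the same interval. IGFBP1 rose by 4.79 ± 0.37 (SE, n = 2 per group, limma adjusted p = 7.66e-05), PRL by 4.17 ± 0.29 (adjusted p = 4.01e-05) and BMP2 by 2.33 ± 0.13 (adjusted p = 1.70e-05). WNT4 rose by 1.76 ± 0.22 (adjusted p = 0.000685), FOXO1 by 1.43 ± 0.14 (adjusted p = 0.000171) and HAND2 by 0.81 ± 0.16 (adjusted p = 0.00654). Between the siRNAs the PRL and WNT4 changes were called different and those of IGFBP1, HAND2, BMP2 and FOXO1 were not, by the interaction test given above with its limits, since the difference between the time courses and that between the knockdown effects are 1 contrast. ESR1 rose by 0.80 ± 0.12 (adjusted p = 0.00156), with its other probe sets at -0.15 and 0.16 not called. Other large rises were those of MMP10 at 4.75 ± 0.17 (adjusted p = 2.52e-06), CXCR4 at 4.58, GADD45G at 4.44, DEPP1, a FOXO target gene, at 4.40 and SST at 4.19. Next were the chemokine gene CCL8 at 4.07, the decidual cytokine gene IL11 at 3.96, IL13RA2 at 3.90, CXCL8 at 3.79 and CEMIP at 3.55. The largest falls were those of MXRA5 at -3.82 ± 0.14 (adjusted p = 2.52e-06), KIF20A at -3.10, the protocadherin gene PCDH9 at -2.86, BIRC5 at -2.51 and RIMS2 at -2.45. Behind them lay IGF2BP3 at -2.40, the calretinin gene CALB2 at -2.39, the mitotic genes CDC20 at -2.38, CCNB2 at -2.35 and HMMR at -2.33, the alarmin gene IL33 at -2.31 and SHCBP1 at -2.19. Group means at 96 h lay under an intensity of 16 for RIMS2, CALB2, CDC20 and IL33. The HAND2 call ended without the siREA 24 h array of culture 1 (0.77) or the siREA 96 h array of culture 2 (0.66), and the calls of HAND2 and ESR1 ended without the culture term (highest adjusted p over the alternatives 0.0701 and 0.159).

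In siREA cells 21 of 23 decidual markers rose with time and 2 were not called, also 21 adjusted over the list alone. The decidual list had a median of 1.43 (camera adjusted p = 1.31e-15, adjusted p = 0.412 with an estimated correlation), with MAOB at 3.49. The 18S ribosomal RNA signal went from 6533 to 2465 in culture 1 and from 6599 to 6336 in culture 2. Of 34 cell division genes 28 fell and 6 were not called, with 28 down and 1 up adjusted over the list alone. For the cell division list the median was -1.36 (camera adjusted p = 6.80e-18, adjusted p = 0.412 with an estimated correlation), with CDC20 at -2.38 and CCNB2 at -2.35. Of 15 cAMP response genes 10 rose and 5 were not called, with 13 up adjusted over the list alone. The cAMP list stood at a median of 0.87 (camera adjusted p = 2.09e-08, adjusted p = 0.636 with an estimated correlation), led by CREM at 1.96 and PPARGC1A at 2.10. Of 20 inflammatory genes 10 rose, 2 fell and 8 were not called, with 12 and 2 adjusted over the list alone. The inflammatory list had a median of 0.81 (camera adjusted p = 0.000389, adjusted p = 0.780 with an estimated correlation), IL11, CXCL8 and IL1B at 3.41 among them. Of 15 cholesterol synthesis genes 9 fell and 6 were not called, with 10 down adjusted over the list alone. For the cholesterol list the median was -0.49 (camera adjusted p = 0.000169, adjusted p = 0.780 with an estimated correlation), led by ACAT2 at -1.21 and HMGCS1 at -1.33. Of 55 respiratory chain subunits 5 fell and 50 were not called, with 1 down adjusted over the list alone. The respiratory chain list stood at a median of -0.18 (camera adjusted p = 0.00167, adjusted p = 0.780 with an estimated correlation), with ATP5MC2 at -0.74 and NDUFA10 at -0.55. Of 26 proteasome subunits 3 fell and 23 were not called, with none adjusted over the list alone. The proteasome list had a median of -0.20 (camera adjusted p = 0.00866, adjusted p = 0.780 with an estimated correlation), with PSMA1 at -0.45 and PSMA4 at -0.43. Of 16 contractile cytoskeleton genes 8 fell, 1 rose and 7 were not called, with 9 and 1 adjusted over the list alone. For the contractile list the median was -0.39 (camera adjusted p = 0.0147, adjusted p = 0.780 with an estimated correlation), with TAGLN at -1.72 and TPM2 at -1.06 down and CCN2 at 2.50 up. Of 11 progestin response genes 4 rose and 7 were not called, also 4 adjusted over the list alone. The progestin list stood at a median of 0.33 (camera adjusted p = 0.0311, adjusted p = 0.780 with an estimated correlation), with ZBTB16 at 1.85 and CDKN1C at 1.01. Of 5 endothelial markers 2 rose and 3 were not called, also 2 adjusted over the list alone. The endothelial list had a median of 0.52 (camera adjusted p = 0.0392, adjusted p = 0.743 with an estimated correlation), with KDR at 2.82 and TEK at 1.08. Without the siREA 96 h array of culture 2 the respiratory chain, contractile, proteasome and progestin list calls ended (adjusted p up to 0.0707, 0.135, 0.135 and 0.139 over the alternatives). The progestin call also ended without the siREA 24 h array of culture 2, with no filter and with the lowest 50% left out. The endothelial call was kept in 9 of 17 alternatives (up to 0.203). It ended without the siREA 24 h or 96 h array of culture 1 or either siGL3 96 h array, with only the arrays compared, with no filter, with the lowest 50% left out and with 1 added. With fry the decidual, cell division and cAMP lists kept their calls for time in siREA cells, the BMP list was called as higher (adjusted p = 0.0308) and the other 7 lists that camera called were not.

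In siREA cells limma called 1154 of 9523 genes as rising and 1002 as falling with time, 327 and 225 of them at least 2-fold. The majority turned to falling genes under quantile normalization (1171 rising, 1375 falling), under median centring (1117 and 1241) and without the siREA 24 h array of culture 2 (606 and 637). Both siRNAs shared 511 rises and 567 falls, where independent draws would give 123.2 and 140.7, against 14 genes that rose in siGL3 and fell in siREA cells and 47 that did the reverse. The total of 2156 was 1320 and 1243 without the siREA 24 h array of culture 1 and culture 2 and 1149 and 1193 without the siREA 96 h array of culture 1 and culture 2.

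Whether knockdown moved the genes that move with time was asked across 9523 genes, which are not independent replicates, by setting the knockdown effect of 1 culture against the siGL3 time course of the other, so that no array was shared. At 24 h Pearson r was 0.0209 and 0.0973 (Spearman rho 0.0936 and 0.143). At 96 h r was -0.350 and -0.189 (rho -0.197 and -0.0955): genes such as CXCL1 and CXCL2 that rose with time in siGL3 cells were lower after knockdown. Within a culture, where the siGL3 array enters both sides, r was 0.175 and 0.0280 at 24 h and -0.309 and -0.470 at 96 h, and simulated data with no true effect gave 0.501 and -0.499 from the shared array alone. The covariance within a culture was 0.0419 and 0.00751 at 24 h and -0.0786 and -0.168 at 96 h, against 0.0238 and -0.0237 in the simulation.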

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

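Of the tests in this part, the comparison of effect sizes at 96 h and 24 h over the whole decidual list, the reading of single leukocyte markers and the restriction to splits that part all pairs were chosen after the results were seen. The knockdown effect differed between 24 h and 96 h by limma's interaction test in 594 genes, and in 160 to 1033 over the settings and 176 to 616 without 1 array. The named genes with a higher effect at 96 h were MATN2 at 4.48, PLXNC1 at 3.39, THSD7A at 3.38, EPYC at 3.34, MGP at 3.26, IGF1 at 2.98, SFRP4 at 2.83, MMP10 at 2.76, ENPP1 at 2.74, MAOB at 2.74, PRL at 2.70, SLC7A8 at 2.49, WNT4 at 2.29 and PHB2 at 1.49. Those with a lower effect were CXCL5 at -4.70, RGS5 at -4.62, CXCL1 at -4.62, CXCL3 at -4.24, C3 at -4.15, CX3CL1 at -3.64, CXCL2 at -3.58, MMP3 at -3.56, CCL7 at -3.28, CCL2 at -3.16, CXCL6 at -3.00 and RGS4 at -2.66. Higher and lower are signed here and do not give effect size. A fall that was larger at 96 h, as for CXCL1, counts as lower, and one that was smaller, as for PHB2, as higher. Other probe sets of PLXNC1, SLC7A8, RGS5 and CX3CL1 gave 1.45, 0.18, -3.52 and -1.73 and were not called (adjusted p = 0.152, 0.635, 0.0938 and 0.210). Further probe sets of PLXNC1, SLC7A8 and RGS5 gave 2.168, 1.69 and -4.025 and were called (limma adjusted p = 0.0453, 0.0312 and 0.0352). The lists that differed between the times, by camera at the preset correlation, were the decidual markers with a median of 0.73, the stromal markers at 0.45, cell division at -0.37, the integrated stress response at -0.24, inflammation at -1.67, cholesterol synthesis at -0.44 and hypoxia and glycolysis at -0.25, and none of them was called with an estimated correlation. With other settings the calls of RGS5, CX3CL1 and THSD7A were kept in 9 of 17, 7 of 17 and 9 of 16 alternatives, with the arrays they rest on named in the report.

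Of 23 decidual markers 9 had a higher knockdown effect at 96 h, 1, SST, had a lower one and 13 were not called. PRL was lower in siREA cells at 24 h, while its rise at 96 h was called in 8 of 18 alternatives and was 0.34 and not called without the siGL3 96 h array of culture 2. The PHB2 transcript recovered from 9.70% and 8.72% of its siGL3 level at 24 h to 31.4% and 23.1% at 96 h. This would shrink effects that track the transcript, rather than enlarge or reverse them. REA protein was not measured, so effects that track the protein are not covered. Of the 10 markers called in the interaction, 30% had opposite signs at the 2 times, with only PRL called at both. This share met neither bound set beforehand. Of the 23 markers, 65.2% in culture 1 and 78.3% in culture 2 had the larger absolute effect at 96 h. Arrays of a group also differed more at 96 h. Their median absolute log2 difference was 0.170 in siGL3 and 0.212 in siREA cells, against 0.13 and 0.157 at 24 h. No share over all genes was set beside these, so the larger effects do not decide on recovery as a cause. A single culture does not carry the pattern, since the smaller of the 2 medians was 0.417. A dependence on REA that changes as differentiation proceeds may underlie the pattern and stays a hypothesis, as off-target effects of the siRNA were not tested and no other siRNA against REA was among these samples.

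Of 20 inflammatory genes 16 were lower in siREA than in siGL3 cells at 96 h, with the smaller culture median at -2.41, so both cultures carried it. Leukocytes in the siGL3 cultures may bring such transcripts, and would lower their markers in siREA cells. The 6 measured of 13 leukocyte markers had a median difference of 0.138 at 96 h, above the bound of -0.2 set beforehand. CD3E at 0.50 and GNLY at 0.45 were called higher (limma adjusted p = 0.0234 and 0.0421), which goes against leukocytes. The rise of the list over both times with fry (adjusted p = 0.0259) goes the same way, but camera did not call it (adjusted p = 0.240). At 96 h alone fry did not call the list. CD74 was at -0.86 (limma adjusted p = 0.0651, not called), which goes with leukocytes. With markers in both directions, of different leukocyte types and at intensities from 14.7 to 104.5 in siGL3 cells against a median of 931 for the inflammatory genes, the median does not decide and leukocytes stay open. An effect of REA loss on inflammatory signalling stays open as a hypothesis, and off-target effects of the siRNA stay untested.

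Over both times knockdown changed 2781 genes. In a model with the split, time and culture as additive terms, the real split of the 8 arrays into 4 and 4 called 1782 genes. Arrays of 1 culture come from 1 donor, and of the 8 splits that part all 4 pairs of a culture and time it was 1, the highest of the others calling 0, so the splits are too few for a share under 0.05. The other 25 splits that could be fitted, which leave pairs together, also called at most 0. Each split but the real 1 put siREA and siGL3 arrays on both sides, so the siRNA effect widened its residual spread. Their 0 calls were thus favoured by design and do not measure chance. An interferon response to siREA beyond that to siGL3 would raise interferon genes, and their median was -0.105. A response to both siRNAs alike would cancel in this comparison and is not covered. Scaling between arrays was checked by quantile normalization, under which 96.6% of calls, 2686 of 2781, kept call and sign. Under median centring 2544 did, and the share of rises moved with both. Most calls therefore do not depend on rescaling the deposited values. These already lay near a common distribution, so any scaling done before deposit stays untested. A broad effect of REA loss may explain the calls and stays a hypothesis, with off-target effects of the siRNA untested.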

How the results depend on the processing

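No called value of a named gene changed sign under any alternative, and of 174 named calls 157 were kept without the culture term, 157 with 1 added before the log, 169 under quantile normalization, 169 under median centring, 172 with no filter, 174 with 64 added, with an intensity trend or with every probe set, and 162 to 173 with 1 array left out. With the lowest 50% left out 131 of 131 testable calls were kept, and with only the arrays compared 118 of 118. The latter fits barely measure a gene's own spread, so genes with large differences tend to stay called and the 118 add little support. The setting with every probe set still read each named gene from its main probe set, so it does not test the gene's other probe sets. Some of those had the opposite sign without a call, at -0.13 for LAMC1 and 0.04 for MMP11 at 24 h and -0.07 for ESR1 at 96 h. Most of the named genes were named for large changes of the same sign in both cultures, which favours kept signs and calls. These shares therefore do not describe all called genes. Leaving out 1 array gave 622 to 2031 called genes for knockdown at 24 h, 911 to 1825 at 96 h, 1751 to 2879 for the average, 1015 to 2296 for time in siGL3 cells, 1149 to 2440 for time in siREA cells and 176 to 616 for the interaction, with the arrays that moved a count by over 1.5 times named in the report; the cause was not tested. The interaction called 191 genes without the culture term, 1033 with an intensity trend, 160 with 1 added and 966 with 64 added, and the cause was not tested. With an estimated correlation 0 lists were called in all 6 comparisons, against 6, 7, 7, 12, 10 and 7 at the preset one. That test rests on 3 residual degrees of freedom and has little power, so its 0 calls do not decide for or against a list. At an unadjusted camera p under 0.05 it gave 1 list for time in siGL3 cells, 2 for time in siREA cells and 0 elsewhere. With fry 0 lists were called at 24 h (6 at an unadjusted p under 0.05), 0 in the interaction (4) and 4 for time in siREA cells, and with 1 added 4 in the interaction; the cause was not tested. Leaving out 1 array gave 6 to 10 lists for time in siREA cells, the 6 without the siREA 96 h array of culture 2. Values not called that changed sign were WNT4 at 24 h (-0.0083 with 64 added, -0.31 to 0.36 without 1 array), PHB2 over time in siGL3 cells (-0.18 to 0.0745 without 1 array) and HAND2 over time in siGL3 cells (-0.17 to 0.32 without 1 array). On each array 27.8% to 30.0% of the probe sets lay under an intensity of 16, and the folds of genes at that level depend on the value added before the log.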

Other observations

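The 29 gene families in this part were chosen after the data were examined, and camera tested them in all 6 comparisons. From 24 h to 96 h, 9 of 13 cathepsins rose in siGL3 cells (median 0.56, adjusted p = 0.000998, adjusted p = 0.441 with an estimated correlation), with CTSS at 2.24 and CTSK at 0.78, and 8 of 13 rose in siREA cells (median 0.68, adjusted p = 0.000115, adjusted p = 0.455 with an estimated correlation), with CTSL at 1.31. Of 25 kinesins 12 fell in siGL3 cells (median -0.48, adjusted p = 0.00485, adjusted p = 0.441 with an estimated correlation), with KIF20A at -2.72 and KIF18B at -1.63, and 9 fell and 2 rose in siREA cells (median -0.30, adjusted p = 0.0182, adjusted p = 0.455 with an estimated correlation), with KIF4A at -1.82. Of 13 dual-specificity phosphatases 6 rose in siGL3 cells (median 0.54, adjusted p = 0.00296, adjusted p = 0.627 with an estimated correlation), with DUSP1 at 1.29, and of 202 zinc finger genes 19 rose and 7 fell there (median 0.12, adjusted p = 0.0233, adjusted p = 0.877 with an estimated correlation). In siREA cells 5 of 7 IGF binding protein genes rose (median 1.02, adjusted p = 0.0182, adjusted p = 0.455 with an estimated correlation), with IGFBP2 at 2.11, and 6 of 23 aminoacyl-tRNA synthetases fell (median -0.19, adjusted p = 0.0232, adjusted p = 0.751 with an estimated correlation), with YARS1 at -0.77.

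After knockdown at 96 h, 10 of 38 histone genes fell and 1 rose (median -0.29, adjusted p = 0.00112, adjusted p = 0.950 with an estimated correlation), with H2AC25 at -1.28, and over both times 14 fell and 2 rose (median -0.20, adjusted p = 0.0469, adjusted p = 0.727 with an estimated correlation). Histone probe sets share sequence between paralogs, so single members are not told apart with certainty. Of 17 tubulins 5 rose at 96 h (median 0.27, adjusted p = 0.0174, adjusted p = 0.993 with an estimated correlation), with TUBB2A at 0.71, and of 13 Wnt ligands and secreted antagonists 5 rose and 1 fell (median 0.42, adjusted p = 0.0174, adjusted p = 0.950 with an estimated correlation), with SFRP4 at 2.30, WNT4 at 2.32 and DKK1 at 1.58. These medians kept their sign under quantile normalization and median centring.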
